A study of Mus musculus with 10 samples.

How the data were processed

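XBP-1 occupancy was measured by chromatin immunoprecipitation and sequencing in mouse liver (strain C57BL/6J, per the labels). The 10 samples were 8 immunoprecipitated libraries, 2 each from fed mice (Fed), fasted mice (Fasted), control mice of the knockout experiment (WT) and mice lacking Ern1 in the liver (Ern1-LKO), and 2 input libraries of liver DNA. The labels do not say how long the fast lasted or whether the WT and Ern1-LKO mice had been fed. They also do not say which samples came from separate animals, so any permutation p-value measures only the spread between these samples, which may be technical. The Fisher's exact tests contrast genes within these libraries and measure no spread between samples.

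The authors deposited 12 peak lists, 1 for each of the 8 libraries and 1 for the pooled libraries of each of the 4 groups. Per the submitters' processing notes, reads were handled with bcl2fastq, FastQC 0.11.3, Bowtie2 2.2.5 and MACS2 2.2.1 on build mm10. The file headers name MACS version 2.1.1.20160309 instead, with single-end tags, 1 tag kept per position, narrow peaks and a q cutoff of 0.05. Per the file headers, Fed and Fasted lists were called against the same input library with 39.67M kept tags (M, 1e6) and 51-bp tags, and WT and Ern1-LKO lists against the other input library with 16.51M kept tags and 50-bp tags. The comparisons therefore ran in separate batches, and groups were compared only within each batch. Ranks and counts given over all 8 libraries, and the overlap of genes between the comparisons, span both batches. The reference signal of each peak caller run is its input library, and the input libraries entered only through those calls.

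Each list gives, per the file headers, a pileup signal at the summit, a fold enrichment, which is the ratio of treatment pileup to the local background, and −log10 p-values and q-values. These values are the authors' own. They were used here to rank, filter or describe peaks within a list, and the median fold of the top peaks was also compared between libraries of the same comparison to weigh enrichment strength. The pileup signal deposited by the authors was not used in any test, and no reads or coverage tracks were analysed here.

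The deposited coordinates were matched to 21887 protein-coding genes of the RefSeq annotation of GRCm38.p6, the assembly of mm10. That table gives the start and end of each gene but neither its strand nor its transcription start sites. The promoter peaks planned at the outset were therefore replaced by gene-end peaks, whose summit lies within 1 kb of either end of a gene. This counts peaks at 3′ ends, misses internal start sites and gives neighbouring genes the same peak. A gene counts in both libraries of a group even where their peaks lie at different sites or ends. A peak list has no strand, so Mroh8 and Rpn2, Catsper2 and Pdia3, and Brca1 and Nbr1 each share a peak.

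Peaks of several libraries were merged into regions where they overlapped by at least 1 bp. Replicate overlap was set beside 100 random placements of the same peaks on their own chromosomes. Peak numbers were compared on the log2 scale with exact two-sided permutation tests, and 2 libraries against 2 cannot give a p below 0.33. Gene lists were tested with two-sided Fisher's exact tests and Benjamini-Hochberg adjustment, either for a gene-end peak in both libraries of a group against all other genes, or for a peak in both libraries of a group and neither of the other against the other genes with a peak in that comparison. Genes are not replicates, so these tests describe these libraries.

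The choices were made before the data were examined: 28 gene lists holding 552 matched genes (1 listed gene, Tf, had no match), 30 genes reported in any case, and the rule for the other named genes. That rule takes up to 10 genes per direction with a peak in both libraries of a group and neither of the other, up to 10 genes with a peak in all 8 libraries, both ordered by mean percentile within the lists, and examples from the gene lists. Predicted genes, with names of the Gm or Rik form, were passed over. The counts of genes among equal numbers of top peaks, the union of 5 secretory lists (125 genes) and the settings that go with it were chosen after seeing the data. All 28 lists had been counted at 698 and at 6258 top peaks before the 5 lists were joined, so the union was picked among many possible groupings.

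Alternatives were stricter limits on −log10 q (5 and 10) and fold enrichment (5), a larger required overlap (50%), a window of 5 kb, the authors' pooled lists, equal numbers of top peaks, the replicate number as a block and leaving out each library. The planned motif search at summits was not run, because it needs a genome sequence, which was not used here. On simulated data, 1500 of 1500 planted shared regions and 2000 of 2000 planted gene-end peaks were recovered. A list given an odds ratio of 10 was called in 34 of 50 simulations of the Fed-only set and in 25 of 50 of the WT-only set, but in 4 of 50 of the Fasted-only set and 0 of 50 of the Ern1-LKO-only set. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.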

Results

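Occupancy of XBP-1, a transcription factor of the unfolded protein response, was mapped in mouse liver to find its targets in liver metabolism. Ern1 encodes the endoplasmic reticulum (ER) kinase and nuclease that splices Xbp1 mRNA into the form translated to the active factor. Fed and fasted livers, and control livers (WT) and livers lacking Ern1 (Ern1-LKO), were each represented by 2 libraries. Kept tags numbered 17.4M and 7.77M in the Fed libraries, 8.38M and 9.62M in the Fasted, 14.07M and 9.18M in the WT and 12.0M and 4.34M in the Ern1-LKO libraries.

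Genes for protein folding in the ER carried gene-end peaks in nearly every library. Of 24 such genes, 24 had a peak in both Fed libraries, 23 in both Fasted, 24 in both WT and 22 in both Ern1-LKO libraries. Across all 8 libraries, 21 of the 24 had a peak, against 340 of 21863 other genes (Fisher's exact test, adjusted p = 1.1e-33). The Ern1-LKO replicate 1 list, with 698 peaks, still held 22 of them. In all, 361 genes had a gene-end peak in all 8 libraries.

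The genes ranked highest over the 8 libraries were Brd2, a bromodomain protein, Tram1, which assists protein translocation into the ER, Dnajc3, an ER co-chaperone, Mia3, needed for export of large cargo from the ER, Txndc5, Rpn2, Pdia6 and Pdia3. Txndc5, Pdia6 and Pdia3 encode members of the protein disulfide isomerase family. Mroh8 and Catsper2 entered the same ranking through peaks shared with Rpn2 and Pdia3. Tram1 (mm10 chromosome 1, 13564693 to 13589910) ranked 1 in 5 libraries, where the fold enrichment reached 115.2 in Fasted replicate 1. Its rank was 2 in Fed replicate 2, 4 in Ern1-LKO replicate 1 and 3 in Ern1-LKO replicate 2. Brd2 (chromosome 17, 34112019 to 34122814) ranked 1 in Fed replicate 2 and in both Ern1-LKO libraries, with folds of 31.7 and 103.2.

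Among the 30 genes fixed beforehand, 11 had a gene-end peak in all 8 libraries: the chaperone gene Hspa5, the co-chaperone gene Dnajb9, Hyou1, Pdia4, Pdia6, Sdf2l1, Creld2, the ER-associated degradation (ERAD) gene Herpud1, the translocon gene Sec61a1, Xbp1 itself and Ddit3. The peak at the Xbp1 gene (gene span chromosome 11, 5520641 to 5525993) had folds of 36.1 and 61.8 in Fed, 59.7 and 27.4 in Fasted, 17.1 and 30.9 in WT, and 9.5 and 33.7 in Ern1-LKO. Sel1l, Syvn1, Srp19 and Atf4 had a peak in 7 libraries, Derl2, Ern1 and Ppargc1a in 6, Sec23b and Dgat2 in 5, Fgf21 and Mttp in 4, Pck1 in 3 and Cpt1a in 2. Edem1, Acacb and Scd1 had a peak only in Fed replicate 1, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, only in WT replicate 1. Alb and Saa1 had none. The peak lists give no measure of the Ern1 deletion itself, and a peak at an Ern1 end appeared in WT replicate 2 and in Ern1-LKO replicate 2.

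**Figure D1:**
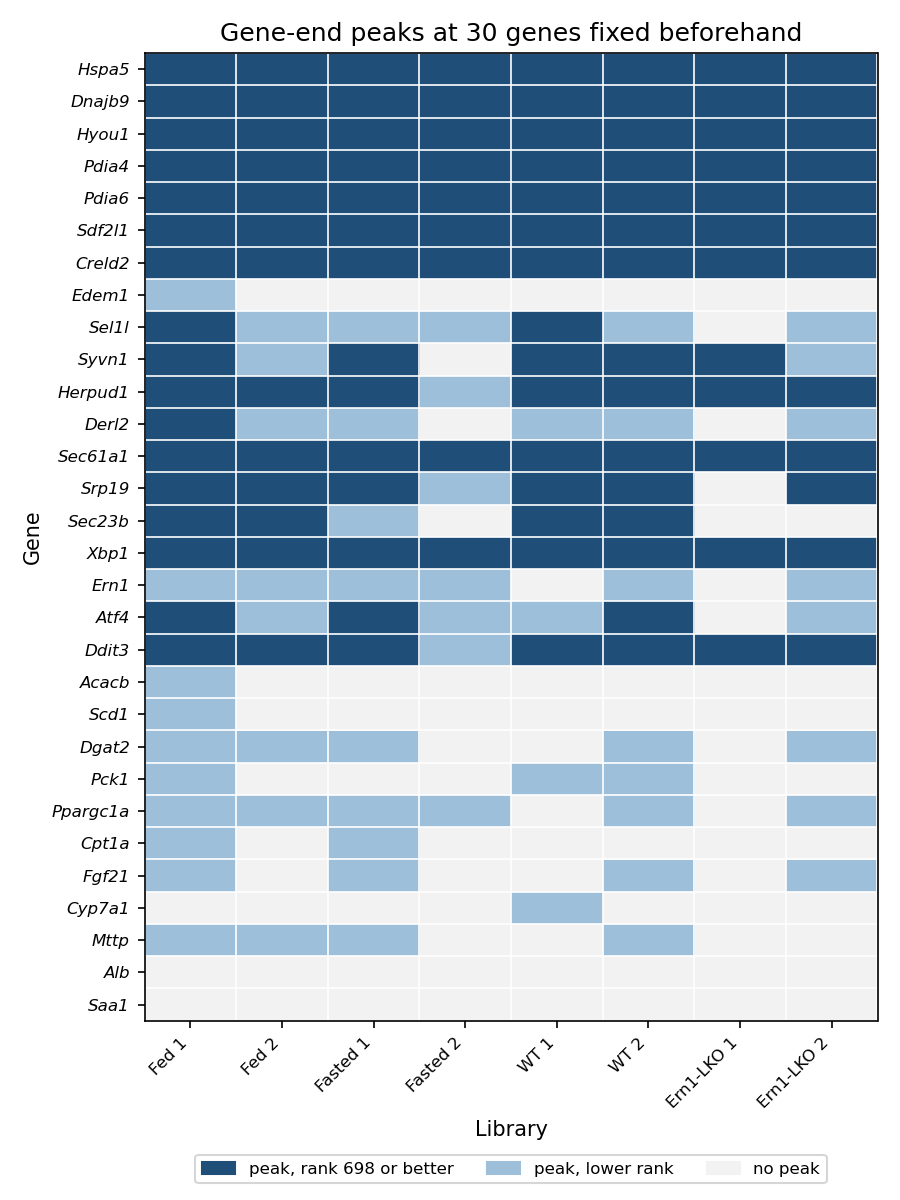
Gene-end peaks at the 30 genes fixed beforehand (rows) in the 8 libraries (columns), with dark cells for a peak ranked 698 or better in its list, light cells for a lower rank and grey for no peak. Folding genes are dark across all 8 libraries, and metabolic genes are mostly light or grey.

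Of all genes, 52.9% had a gene-end peak in both Fed libraries, 25.4% in both Fasted, 10.3% in both WT and 2.4% in both Ern1-LKO libraries. Secretory-pathway lists beyond folding were also called in each group. ER-Golgi transport genes had peaks in 30 of 31 cases in Fed, 17 in Fasted, 30 in WT and 9 in Ern1-LKO. For translocon and ER targeting the counts were 22, 13, 22 and 9 of 23, for ERAD 18, 11, 19 and 6 of 20, and for N-glycosylation 22, 16, 19 and 6 of 27. The adjusted p was at most 0.034 for each of these lists in each group (Fisher's exact test). The translocon call in Fasted was lost with 5 kb windows, the ERAD call in Fasted at a −log10 q of 5 and the N-glycosylation call in Ern1-LKO without replicate 1 (Fisher's exact adjusted p = 0.13, 0.053 and 0.053). Genes of the other unfolded protein response arms had peaks in 17 of 20 cases in Fed, 8 in Fasted, 8 in WT and 4 in Ern1-LKO, and passed in all but Fasted (Fisher's exact adjusted p = 0.39), though not in Ern1-LKO with the pooled list (0.073), and they did pass in Fasted with the pooled list (0.010) and without replicate 2 (0.0015). These counts rest on lists of very different length and do not compare the groups.

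With 1 kb windows and all peaks of both libraries, other lists were called in at most 2 groups. Other settings gained further calls, of which only those in Fed are listed here. In Fed, autophagy and lysosome genes (18 of 20), respiration (21 of 24), proteasome (21 of 24), cytosolic ribosomal proteins (20 of 24), the circadian clock (15 of 18) and cholesterol synthesis and uptake (16 of 20) lay above the other genes. Acute-phase genes (4 of 20), bile acid metabolism (3 of 15), hepatocyte markers (4 of 18), Kupffer cell markers (3 of 15), lymphocyte markers (2 of 15) and muscle genes (5 of 20) lay below them. Of all genes, 52.9% had a peak in both Fed libraries. Among the 698 top peaks of each Fed library, the lists lying above held few genes. These were 1 and 4 for autophagy, 0 and 0 for respiration and for the proteasome, 2 and 0 for ribosomal proteins, 2 and 2 for the clock and 1 and 1 for cholesterol. With the pooled Fed list none of these 6 lower lists was called, and with 5 kb windows hepatocyte markers alone were. Bile acid, Kupffer cell and muscle lists also lost the call without replicate 1 (Fisher's exact adjusted p = 0.062, 0.17 and 0.23) and without replicate 2 (0.67, 0.25 and 0.15), bile acid metabolism at a −log10 q of 5 (0.056) and acute-phase genes without replicate 2 (1). Cholesterol genes lost it with 5 kb windows and without replicate 1 (Fisher's exact adjusted p = 0.11 and 0.066). In Fasted, autophagy genes (12 of 20) lay above and hepatocyte markers (0 of 18) below, calls lost with 5 kb windows and at a −log10 q of 5 respectively (Fisher's exact adjusted p = 0.095 and 0.053). In WT, lipogenesis genes (8 of 24) lay above, but not at a −log10 q of 5, with the pooled list or without replicate 1 (Fisher's exact adjusted p = 0.051, 0.19 and 0.20). No call was made in Fed for lipogenesis (17 of 24), gluconeogenesis (12 of 18), fatty acid oxidation (15 of 22), glycolysis (9 of 16), lipoprotein assembly (7 of 14), DNA repair (15 of 20), endothelial (4 of 15), stellate (7 of 15) and cholangiocyte markers (4 of 10) or neuronal genes (7 of 20). Of these, lipogenesis was called with 5 kb windows, the pooled list and without replicate 2 (Fisher's exact adjusted p = 0.036, 0.0013 and 0.0012), DNA repair with 5 kb windows and without replicate 2 (0.036 and 0.022), gluconeogenesis, fatty acid oxidation and lipoprotein assembly without replicate 2 (0.040 each), and neuronal genes, as lower, at a −log10 q of 5 (0.0065).

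Libraries of the same group gave lists of very different length. Fed lists held 82975 and 47357 peaks, Fasted 53973 and 19237, WT 6258 and 30327, and Ern1-LKO 698 and 30796. Of the shorter list in each group, 60.6% of peaks in Fed, 88.2% in Fasted, 41.3% in WT and 94.0% in Ern1-LKO were overlapped by the other list, against at most 2.85% in random placements. The placements ran over whole chromosomes, while 71.6% of the Ern1-LKO replicate 1 peaks lay at gene ends. They therefore understate the overlap of unrelated lists that both favour gene ends. Gene-end peaks made up 25.3% ± 4.4 of the list in Fed (SD, n = 2), 28.1% ± 1.8 in Fasted, 38.6% ± 2.8 in WT and 54.0% ± 24.9 in Ern1-LKO.

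**Figure D2:**
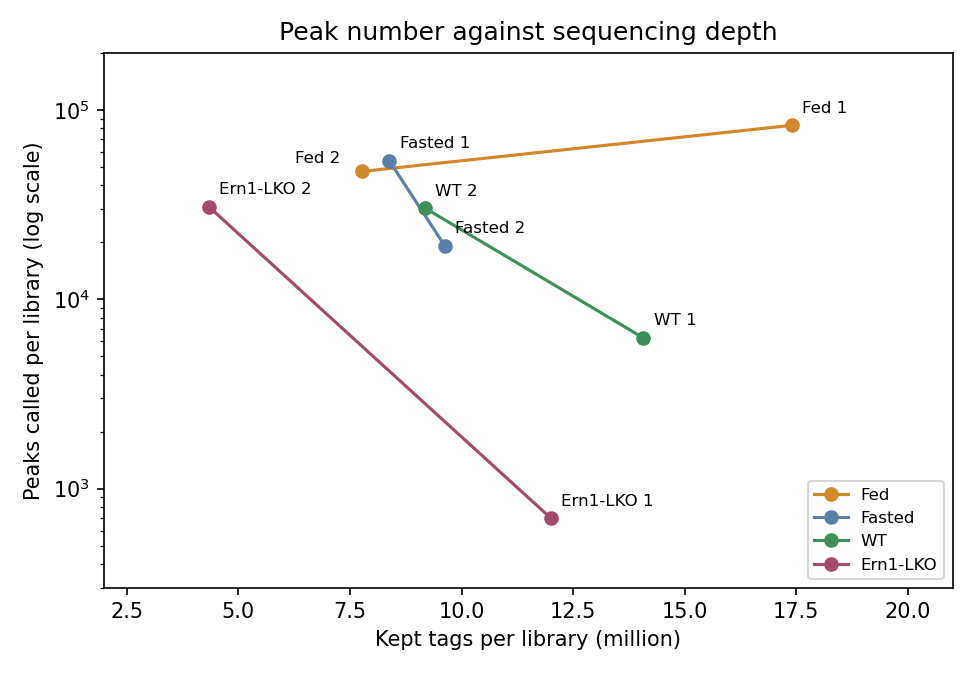
Number of peaks called per library (log axis) against kept tags (M), with points for libraries and lines joining the libraries of a group. Ern1-LKO replicate 1 had 698 peaks from 12.0M tags and Ern1-LKO replicate 2 had 30796 from 4.34M.

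Fed and Fasted livers were compared to ask which XBP-1 sites change with feeding. Regions called in both Fed and neither Fasted library numbered 2588, and regions called in both Fasted and neither Fed library 672. Leaving out a library drops a condition of this rule, so the counts can only stay or rise. Without Fed replicate 1 they were 10305 Fed-only and 939 Fasted-only regions, and without Fed replicate 2 49831 and 5651. They were 16870 and 1772 without Fasted replicate 1, and 2723 and 12085, with the larger side changed, without Fasted replicate 2. In genes, 294 had a gene-end peak in both Fed and neither Fasted library and 26 the reverse. Leading the Fed-only genes were Plxnb2, Golph3, a Golgi phosphoprotein, Chd7, a chromatin remodeller, Ncoa2, a nuclear receptor coactivator, Sin3a, Gemin6, Brca1 with its neighbour Nbr1, Ppp1r42 and Lrba. Plxnb2 (chromosome 15, 89155546 to 89182018) had folds of 12.1 and 15.8 in the Fed lists. Leading the Fasted-only genes was the histone acetyltransferase gene Kat6b (chromosome 14, 21499216 to 21672478), with folds of 17.2 and 15.2, followed by others that included Spred2, Hipk3, Pds5a, Cenpv, LOC115488470, Pnrc1, Tbx18 and Zpld2.

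The gene lists held few Fed-only members: Psma1 of the proteasome, Brca1 and Trp53 of DNA repair, Asgr1 among hepatocyte markers, Tyrobp among Kupffer cell markers, Lcn2 of the acute phase and Nfil3 of the clock. No list passed in either direction (0 lists after Benjamini-Hochberg adjustment, 1 at an unadjusted p under 0.05, Fisher's exact test). Leaving out Fed replicate 2 gave 2 lists, bile acid metabolism and acute phase among Fed-only genes, and leaving out Fasted replicate 1 gave 1, ER folding. Among all peaks the split by feeding did not stand apart from the other ways of dividing the 4 libraries. Replicates 1 against replicates 2 gave 5824 and 968 regions, and the crossed split 50 and 4652. With 19237 top peaks per library, 910 regions were Fed only and 1817 Fasted only, so the larger side changed. Replicates 1 against replicates 2 gave 921 and 2004 regions there, and the crossed split 160 and 878. Genes with a gene-end peak stayed at more Fed only (456) than Fasted only (125). With 698 top peaks per library, a setting chosen after seeing the data, splits were compared in the 736 genes present in both comparisons. The feeding split stood apart there, at 121 Fed-only and 39 Fasted-only genes. Replicates 1 against replicates 2 gave 16 and 4 genes, and the crossed split 0 and 13. Mean peak number was 65166 in Fed and 36605 in Fasted, and the geometric mean 1.95-fold higher in Fed (0.96 on the log2 scale, 0.56 without Fed replicate 1, 1.70 without Fasted replicate 1 and 0.22 without Fasted replicate 2, exact permutation p = 0.67, smallest possible 0.33).

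Among the 698 top peaks of each library, a number set by the shortest list, Fed libraries held more secretory-pathway genes than Fasted libraries. Of the 125 genes of the 5 lists, 97 and 80 had a gene-end peak in Fed and 65 and 36 in Fasted, which is 88.5 ± 12.0 against 50.5 ± 20.5 (SD, n = 2). ER-Golgi transport genes numbered 24 and 22 in Fed against 15 and 4 in Fasted, and translocon genes 20 and 17 against 12 and 6. ERAD genes overlapped, at 14 and 6 against 7 and 4, and folding genes were at 24 and 24 against 23 and 16. This count was chosen after seeing the data, its exact permutation p of 0.33 is the smallest the design allows, and the difference of 38.0 genes was 23.5 without Fasted replicate 2. Among the same top peaks, 15 of the 100 secretory genes present were Fed only (15.0%), against 147 of 1175 other genes (12.5%), and 0 were Fasted only, against 58 of 1175 (4.9%). With all peaks, 123 and 116 of the 125 genes had a gene-end peak in Fed and 118 and 80 in Fasted. Fasted replicate 1 thus had a peak at nearly all of these genes, many below the top 698.

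**Figure D3:**
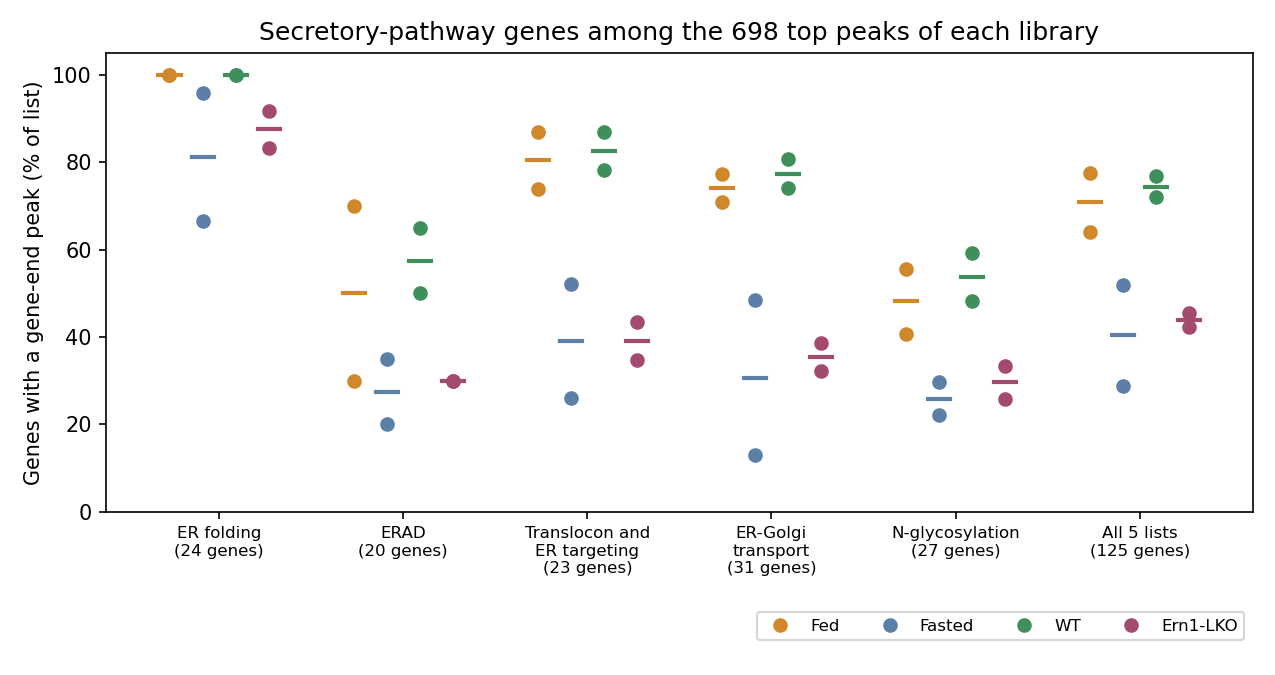
Percentage of each secretory-pathway list with a gene-end peak among the 698 top peaks, with points for the 2 libraries of each group and bars for their mean. For all 125 genes the Fed and WT points, at 80 to 97 genes, lie above the Fasted and Ern1-LKO points, at 36 to 65 genes.

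WT and Ern1-LKO livers were compared to ask which XBP-1 sites depend on Ern1. Regions called in both WT and neither Ern1-LKO library numbered 220, and no region (0) was called in both Ern1-LKO and neither WT library. Leaving out a library can again only keep or raise such counts, of regions or of genes. The WT-only and Ern1-LKO-only regions numbered 9963 and 0 without WT replicate 1 and 3878 and 205 without WT replicate 2. They numbered 1976 and 3 without Ern1-LKO replicate 2, and 240 and 10221, with the larger side changed, without Ern1-LKO replicate 1. In genes, 154 were WT only and 4 Ern1-LKO only. WT-only genes were led by Cope, a subunit of the COPI coat, Itfg2, Chid1, Tmem125, Sec23b, a COPII coat subunit, Prpf4b, Gmppa, Bet1, a SNARE of the early secretory pathway, Parn and Lamtor2. Sec23b (chromosome 2, 144556229 to 144590753) had folds of 7.5 and 28.8 in WT. The 4 Ern1-LKO-only genes were Pnrc1, Tulp1, LOC115488470 and Klf13. None of them rests on a region called in both Ern1-LKO and neither WT library, since there was no such region. Either their Ern1-LKO peaks lay in different regions, or a WT peak overlapped with its summit outside the window. Pnrc1 and LOC115488470 were also among the Fasted-only genes.

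ER-Golgi transport was over-represented among WT-only genes, with 6 of 30 members present (adjusted p = 0.00011, Fisher's exact test). These were Cope, Sec23b, Bet1, Sec24b and Sec13, both of the COPII coat, and Sar1b, its GTPase. Gluconeogenesis followed with 3 of 15 (Fisher's exact adjusted p = 0.024): Pck1, Tat, the tyrosine aminotransferase gene, and Got1, the aspartate aminotransferase gene. Pck1 (chromosome 2, 173153073 to 173159274) had folds of 9.4 and 2.7, but the summits lay at opposite ends of the gene (173152692 and 173160074). The weaker peak ranked 30314 of 30327. The strongest gene-end peaks of the WT libraries thus mark no shared site at this gene, and weaker peaks were not compared. Other list members among WT-only genes included Sec11a of the translocon list, Os9 of ERAD, Atf6, Brca1, Nr0b2 of bile acid metabolism and Orm1 of the acute phase. Neither list was called with 5 kb windows (Fisher's exact adjusted p = 0.17 and 0.059), with 698 top peaks (0.10 and 1) or without WT replicate 1 (1 and 0.54). Without Ern1-LKO replicate 2 the gluconeogenesis call was also lost (Fisher's exact adjusted p = 1), and 5 lists were called, while ER-Golgi transport rose to 20 genes.

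Among all peaks the genotype split, at 220 and 0 regions, was far below replicates 1 against replicates 2, at 10 and 17325, and the crossed split gave 4 and 1. With 698 top peaks per library the genotype split stood apart, at 157 WT-only and 122 Ern1-LKO-only regions, against 33 and 51 for replicates 1 against 2 and 4 and 19 for the crossed split. Secretory-pathway genes among these top peaks numbered 96 and 90 in WT and 57 and 53 in Ern1-LKO, or 93.0 ± 4.2 against 55.0 ± 2.8 (SD, n = 2). ER-Golgi transport genes were at 25 and 23 against 10 and 12, translocon genes at 18 and 20 against 10 and 8, ERAD genes at 13 and 10 against 6 and 6, N-glycosylation genes at 16 and 13 against 9 and 7, and folding genes at 24 and 24 against 22 and 20. Of the 103 secretory genes present, 24 were WT only (23.3%), against 138 of 1166 other genes (11.8%), and 0 were Ern1-LKO only, against 103 of 1166 (8.8%). This count too was chosen after seeing the data, and its exact permutation p of 0.33 is the smallest possible. With all peaks, 115 and 118 of the 125 genes had a gene-end peak in WT and 57 and 104 in Ern1-LKO. The 57 come from the full list of Ern1-LKO replicate 1, which holds only 698 peaks. Ern1-LKO replicate 2 thus had a peak at most of these genes, many below the top 698. Mean peak number was 18292.5 in WT and 15747 in Ern1-LKO, and the geometric mean 2.97-fold higher in WT (1.57 on the log2 scale, exact permutation p = 1.0), with the order reversed without Ern1-LKO replicate 1 (−1.16 on the log2 scale). Without WT replicate 1, WT replicate 2 and Ern1-LKO replicate 2 the log2 ratio was 2.71, 0.43 and 4.30.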

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

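All tests in this part were chosen after the values they use had been seen. Peaks on unplaced or unlocalised sequences, which count in the peak and region totals but enter no gene test, numbered 58 in Fed replicate 1, 69 in Fed replicate 2, 82 in Fasted replicate 1, 45 in Fasted replicate 2, 5 in WT replicate 1, 36 in WT replicate 2 and 37 in Ern1-LKO replicate 2. Each count is above 3, the limit that a count of 0 allows, which takes no account of the length of the list.

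Secretory-pathway genes were fewer among the 698 top peaks in Fasted and Ern1-LKO than in Fed and WT libraries, a pattern picked out after all 28 lists had been counted. Over the 3 pairs in which the Fed or WT library had fewer kept tags, it still held 30.7 ± 14.6 more genes (SD). Lower depth thus did not bring fewer genes in these pairs. The pairs share libraries, and each Fed or WT library held more of these genes than each library it was compared with. Any choice of pairs therefore gave a mean above 0, and a part played by depth is not excluded. Over the 4 pairs in which the Fed or WT library had the lower median fold among top peaks, it held 37.8 ± 19.3 more genes (SD), and the same limits hold. WT replicate 1 with Ern1-LKO replicate 2 was the only such pair of the knockout comparison. Ern1-LKO replicate 1, with the lowest median fold (5.4), entered none, so weaker enrichment is not excluded. With 283 gene-end peaks per library, which removes the many top peaks of Fasted replicate 2 away from gene ends, the smaller difference was still 29.0. Lower XBP-1 signal at these genes with fasting and without Ern1 may account for the lower counts. Permuting labels within both comparisons gave an exact permutation p of 0.056, the smallest that its 36 assignments allow. With 2 libraries per group, lower signal therefore stays open.

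Folding genes had peaks in both Ern1-LKO libraries, with 19 of 24 among the top peaks of both. Signal at the ends of all highly expressed genes does not account for their place among the top peaks. Ribosomal, respiratory and proteasome genes, taken as highly expressed, gave 1 of 72 there in each library (larger Fisher's exact p = 9.8e-16). The test bears on rank and not on the presence of a peak. With all peaks, Ern1-LKO replicate 2 had 17, 14 and 15 of 24 of these genes, and 24 of 24 folding genes. Ern1-LKO replicate 1 had 1, 0 and 0, and 22 folding genes. Another factor at the same sites, or XBP-1 left in these livers, may account for the peaks; the 19 genes cannot tell these apart, since neither the Ern1 level nor a second antibody was analysed here.

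Peak numbers differed 2.81-fold between the Fasted libraries, 4.85-fold between the WT and 44.12-fold between the Ern1-LKO libraries, and 1.75-fold between the Fed libraries, against 1.95-fold between Fed and Fasted and 2.97-fold between WT and Ern1-LKO (geometric means). The deeper library had more peaks in 1 of the 4 groups, Fed, with 2.24 times the tags and 1.752 times the peaks. In Fed, depth and the share of duplicate tags rose together and cannot be told apart. Ern1-LKO replicate 1 had 2.76 times the tags and 0.023 times the peaks of replicate 2. Depth thus does not account for the differences within Fasted, WT and Ern1-LKO. The library with the higher share of duplicate tags had more peaks in 4 of 4 groups, which chance gives with a two-sided p of 0.125, so a difference in recovered DNA stays open. No biological explanation was tested.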

How the results depend on the processing

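The top-peak counts of secretory genes and their settings were chosen after seeing the data, as was the setting of 698 top peaks for the Fed and Fasted regions. With equal numbers of top peaks, the difference in secretory genes kept its direction in each setting run. It ran from 28.0 to 40.0 genes for Fed against Fasted (35.0 at 6258 top peaks) and from 32.0 to 38.0 for WT against Ern1-LKO. The knockout comparison was not made at 2000 or 6258 top peaks because the list of Ern1-LKO replicate 1 is shorter. Leaving out each library gave 23.5 to 52.5 and 35.0 to 41.0 genes. With all peaks the Fed and Fasted libraries overlapped, at 123 and 116 against 118 and 80 genes. WT and Ern1-LKO libraries stayed apart, at 115 and 118 against 57 and 104, but the 57 come from a list of only 698 peaks. Peak numbers reversed, at −0.09 (log2) for Fed against Fasted at a −log10 q of at least 10, and −0.06 for WT against Ern1-LKO with the authors' pooled lists, with leave-one-out values from −1.16 to 4.30. The larger of the Fed-only and Fasted-only region counts also changed sides, at 654 against 997 with a fold of at least 5 and 910 against 1817 at equal numbers of top peaks, and at 2723 against 12085 without Fasted replicate 2; WT-only and Ern1-LKO-only regions did so at 240 against 10221 without Ern1-LKO replicate 1. The cause was not tested. With the replicate number as a block the log2 ratios were 0.96 ± 0.48 and 1.57 ± 2.25 (SD over the 2 numbers). The labels do not pair animals. Deviations of same-numbered libraries correlated at −0.21 and 0.11 over all peaks, and at 0.13 and 0.09 at equal numbers of top peaks (19237 and 698). A block cannot move the secretory difference of 38.0 genes in this balanced layout.

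Regions in both Fed and neither Fasted library numbered 1214 at a −log10 q of 5 and 167 at 698 top peaks, and 2723 to 49831 when leaving out a library; the reverse numbered 1110 at a −log10 q of 5, 77 at 698 top peaks, and 939 to 12085. WT-only regions were 132 at a fold of 5 and 240 to 9963 when leaving out a library. Ern1-LKO-only regions were 122 at equal numbers of top peaks and 0 to 10221 when leaving out a library. Counts with a library left out can only stay or rise, since a condition of the rule is dropped. A reciprocal overlap of 50% left 953 regions in both WT and 100 in both Ern1-LKO libraries, and a replicate overlap of 48.5% in Fed, 67.1% in Fasted, 15.2% in WT and 14.3% in Ern1-LKO. The pooled lists held 84544, 41795, 13841 and 14428 peaks in Fed, Fasted, WT and Ern1-LKO.

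Called lists per group were 10 with the pooled Fasted list, and leaving out a replicate number gave 6 to 10 in Fasted and 9 to 11 in WT. Counting calls in either direction over the 4 groups, 1 was gained and 4 lost at a −log10 q of 5, 7 and 8 with 5 kb windows, 17 and 8 with the pooled lists, 13 and 6 without replicate 1 and 13 and 4 without replicate 2. Lists among Fed-only or Fasted-only genes were 0 to 2 when leaving out a library. Lists among WT-only or Ern1-LKO-only genes were 0 with 5 kb windows, 1 at a −log10 q of 5, 0 at equal numbers of top peaks and 0 to 5 when leaving out a library. With 5 kb windows gene-end shares were 44.5% in Fed, 44.3% in Fasted and 56.0% in WT; with equal numbers of top peaks they were 76.9%, 59.1% and 68.6%. Of the 30 genes fixed beforehand, 9 changed their number of libraries with 5 kb windows and 6 at a −log10 q of 5. The motif search was not run. Peak number followed depth in Fed only: the deeper library had more in 1 of 4 groups.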

Other observations

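All tests in this part were chosen after seeing the data, except the bound for other splits, which was set before its values were computed. Genes in the top peaks of both Fed and neither Fasted library, and of both WT and neither Ern1-LKO library, were drawn from separate libraries and inputs. They shared 60 genes, where 24.3 would be shared by chance among the 736 genes present in both comparisons (Fisher's exact p = 4.8e-16). Among them were Sec23a, Sec23b and Sec31a of the COPII coat, Copg1 of the COPI coat, Gosr2, a Golgi SNARE, Ssr2, Ssr4 and Spcs1 of ER translocation and signal peptide cleavage, Ganab and Pgm3 of glycan processing and sugar synthesis, and Ubxn4 of ERAD, making 11 genes of the secretory lists. The Fasted-only and Ern1-LKO-only sets shared 9 genes, where 2.0 would be shared by chance (Fisher's exact p = 6.8e-05), and 0 of them were in the secretory lists. The genes named here were chosen after their values were seen. Those 9 were Bzw1, Elf1, H2-K1, Myo18a, Ppm1a, Tbl1xr1, Ube2g1, Vps37d and Wbp4. Neighbouring genes can share a peak in both sets. Mrps18b and Ppp1r10 shared theirs in the Fed libraries, and the ends of Elf1 and Wbp4 overlap. These tests therefore count some peaks more than once, and the overlaps in genes overstate those in separate sites.

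A hypothesis is that fasting and loss of Ern1 lower XBP-1 signal at some of the same genes. Opposite sets shared 1 gene (Fed only and Ern1-LKO only) and 2 genes (Fasted only and WT only). Among 7 other pairs of splits with an expected overlap of at least 1 gene, the highest odds ratio was 1.33, below the lower of the matched odds ratios, 5.86. Of these 7, 2 are the opposite sets, which can only be low where the matched sets overlap, and the other 5 had expected overlaps of 1.5 to 3.2 genes, so they exclude little. Genes are not replicates, and a feature of sample quality shared by the Fed and WT libraries may produce the overlap, so the hypothesis stays open.

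Acute-phase genes with a gene-end peak numbered 13 and 4 of 20 in the Fed libraries, where 63.0% and 55.3% of all genes had one, 3 and 1 in the Fasted (57.9% and 25.8%), 8 and 3 in the WT (11.1% and 51.4%) and 0 and 2 in the Ern1-LKO libraries (2.5% and 46.8%).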
